A study of Mus musculus with 13 samples.

How the data were processed

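Total RNA from 13 mouse samples was measured on 1 array each. Of these, 11 were clones isolated from mouse embryonic fibroblasts (MEF) after infection with sets of reprogramming factors, 1 was a mouse embryonic stem cell (mESC) sample of the strain CGR8, and 1 was the MEF population at passage 2. Per the labels' protocols, 300 ng of RNA per sample was labelled with the Affymetrix whole-transcript cDNA kit, and every RNA integrity number was above 9. The platform annotation names an Affymetrix Mouse Gene ST array, whose probe sets read along the whole transcript.

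The deposited table holds log2 expression values per probe set, 1 column per array and no pooled column. The authors made these log2 values with RMA, per the submitters' processing notes, a method that corrects background, normalizes the arrays to one distribution and summarises the probes of a set. Its version is not given in the sources used here. Values ran from 2.33 to 13.96 and array medians from 6.80 to 6.92. The table has 19619 probe sets, which is part of the array's design, and the filter behind it is not given in the sources used here. A gene without a measurement here was therefore not analysed, and nothing is said of its level. No background call comes with the values, and the level of the dimmest 25% of genes (5.68) is not a detection limit. A difference is called a lower bound where the lower side is under that level, and its size uncertain where both sides are. This holds whether or not it is repeated at each value. Such a bound concerns the point estimate and not its sampling error, so a difference that did not pass may be smaller. Array data have no read depth, and the number of arrays limits the precision.

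Probe sets were named through the platform annotation. It gave 1 gene symbol for 16200 probe sets, several for 843 and none for 2576, and only those with 1 symbol were used. Symbols were updated through the gene identifier with a RefSeq gene table of the mouse assembly GRCm38.p6, which matched 16156 of them, and 44 kept the annotation's symbol. That table was also used for chromosome and gene order, and none of its coordinates is printed. Each gene was represented by its probe set with the highest mean over the 13 arrays, which left 14876 genes, 769 of them with several probe sets.

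Groups were taken from the sample titles: 3 OKS clones (Oct4, Klf4 and Sox2), 5 OKS+F+G clones (the same with Foxa2 and Gata4) and 3 OKSM clones (OKS with Myc). The OKS+F+G clones carry the numbers 1, 2, 3, 5 and 6. A model with 1 mean per group was fitted to the 11 clone arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the groups shared one estimate of the spread. The 4 contrasts were OKS+F+G against OKS, OKSM against OKS, OKS+F+G against OKSM, and OKS+F+G against the mean of the OKS and OKSM group means. Values of p were adjusted by the Benjamini-Hochberg method over all genes, and an adjusted p under 0.05 was called. The single mESC and MEF arrays entered no test.

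Before the data were examined, 21 gene lists with 465 entries were fixed, of which 406 entries were measured. Each list was tested in each contrast with limma's camera at a preset correlation between genes of 0.01, which compares a list with all other genes, and adjusted over the 21 lists. Camera with a correlation estimated from the data and fry were run as alternatives. For each list, members were counted after adjustment over all genes and also adjusted over the list alone. For each clone, the Pearson correlation across genes with the mESC array and with the MEF array was computed. A position between the references was fitted by least squares over the 1781 genes at least 2 apart (log2) between them, from 0 for MEF to 1 for mESC. These measures and the means of 6 lists were compared between groups with exact two-sided permutation tests. They made a family of 27 comparisons, adjusted by the Benjamini-Hochberg method. With 3 clones against 3 the smallest p is 0.1, and with 3 against 5 it is 0.0357.

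Named genes were chosen by a rule fixed before the data were examined. For each contrast they are the 6 introduced factors, the 10 largest positive and 10 largest negative log2 differences among called genes whose groups did not overlap, and for each list up to 4 members with the smallest adjusted p between OKS+F+G and OKS clones. Predicted genes, olfactory receptor (Olfr) and vomeronasal receptor (Vmn) genes were left out of the largest differences. Between the single mESC and MEF arrays, the 10 largest differences each way were named, with Nanog, Cdh1, Thy1 and Col1a1 on every array. Against each reference array, the 5 genes each way with the widest gap to the nearest clone were named. Genes named outside this rule are said to be so.

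The alternatives were fits on the groups of a contrast alone, a trended and robust eBayes, array weights, a further quantile normalization, arrays centred on their medians, removal of the dimmest 25% of genes (mean under 5.68, which left 11157 genes), other handling of probe sets, clone number as a block, and omission of each clone in turn. Added after the data were seen were the average of OKS clones 1 and 2 in place of both, and a fit without the 471 X-linked genes. The fit was tested on simulated data with 200 changed genes among 14876, 100 at each size. For OKS+F+G against OKS it recovered 78% of genes changed by 1 (log2) and 94% of those changed by 2, with 9 false calls. The values were 64% and 94% with 10 false calls for OKSM against OKS, 68% and 89% with 5 for OKS+F+G against OKSM, and 82% and 95% with 7 for OKS+F+G against the mean, and no recovered gene had the wrong sign. These shares describe the simulated data alone and not the power in the real clones. Among the latter, OKS clone 3 correlated with OKS clones 1 and 2 at only 0.891 and 0.873. Per-clone measures and figures were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.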

Results

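Gene expression was profiled in clones derived from mouse embryonic fibroblasts that had been infected with reprogramming factors, picked as colonies and expanded separately. The collection comprised 3 clones made with Oct4, Klf4 and Sox2 (OKS), 5 clones made with these and the endoderm transcription factors Foxa2 and Gata4 (OKS+F+G), and 3 clones made with OKS and Myc (OKSM). A single array of mouse embryonic stem cells and a single array of the fibroblasts served as references and have no replicates. Clones and stem cells were grown in medium with 10% serum and 1000 U/ml of leukemia inhibitory factor. The sources used here do not say whether the colonies of a group came from separately infected cells, so p-values measure the spread between these samples. In the table, 14876 genes could be tested.

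Within groups, the Pearson correlation across genes between clones was 0.973 to 0.983 for OKSM and 0.941 to 0.982 for OKS+F+G. Among OKS clones it was 0.987 between clones 1 and 2, and it was 0.891 and 0.873 between these and clone 3. With the OKS+F+G clones, OKS clones 1, 2 and 3 correlated at means of 0.946, 0.933 and 0.930. The median SD per gene between clones was 0.21 (log2) in OKS, 0.19 in OKS+F+G and 0.14 in OKSM. Genes are not independent replicates in such correlations. OKS clone 3 also differed from clones 1 and 2 in Xist, the RNA that coats the inactive X chromosome, which was 9.90 in clone 3 against 4.40 and 4.38 in clones 1 and 2. The other 8 clones had Xist values of 9.18 to 9.92, the MEF array 8.99 and the mESC array 4.32. In OKS clones 1 and 2, 79.2% and 76.6% of 380 chromosome 19 genes lay above the mean of the other clones, against 42.9% to 56.2% and 41.3% to 52.7% on the other autosomes.

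The introduced factors were examined first, as a check on the labels. Pou5f1, which encodes Oct4, was 11.65 ± 1.53 (SD, n = 3) in OKS, 12.44 ± 0.31 (SD, n = 5) in OKS+F+G and 13.11 ± 0.05 (SD, n = 3) in OKSM clones. It was 4.49 on the MEF array and 11.80 on the mESC array, and the lowest clone, OKS 2, was at 9.95. Klf4 was 10.58 ± 0.07, 10.47 ± 0.22 and 10.50 ± 0.10 in the same groups, against 9.06 in MEF and 9.81 in mESC. Myc was 11.32 ± 0.07 in OKSM clones against 9.12 ± 0.40 in OKS, a difference of 2.21 (log2, SE 0.37, limma adjusted p = 0.00268), and 9.00 ± 0.66 in OKS+F+G. Sox2 was 4.31 ± 0.52, 4.22 ± 0.24 and 4.33 ± 0.19 in the OKS, OKS+F+G and OKSM clones, near the MEF value of 4.34, while the mESC array read 11.30. Foxa2 was 5.49 ± 0.12 in OKS+F+G and 5.51 ± 0.08 in OKS clones (limma adjusted p = 0.96), and Gata4 was 5.78 ± 0.13 and 5.72 ± 0.14 (limma adjusted p = 0.91). The probe sets of Pou5f1 and Myc thus went with the labels, and those of Sox2, Foxa2 and Gata4 were on average not above the MEF array's values in the clones labelled with them, the largest excess in 1 clone being that of Sox2 in OKS 3 (0.57). Whether the latter probe sets read the introduced sequences is not given in the sources used here, so Foxa2 and Gata4 check no label.

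**Figure D1:**
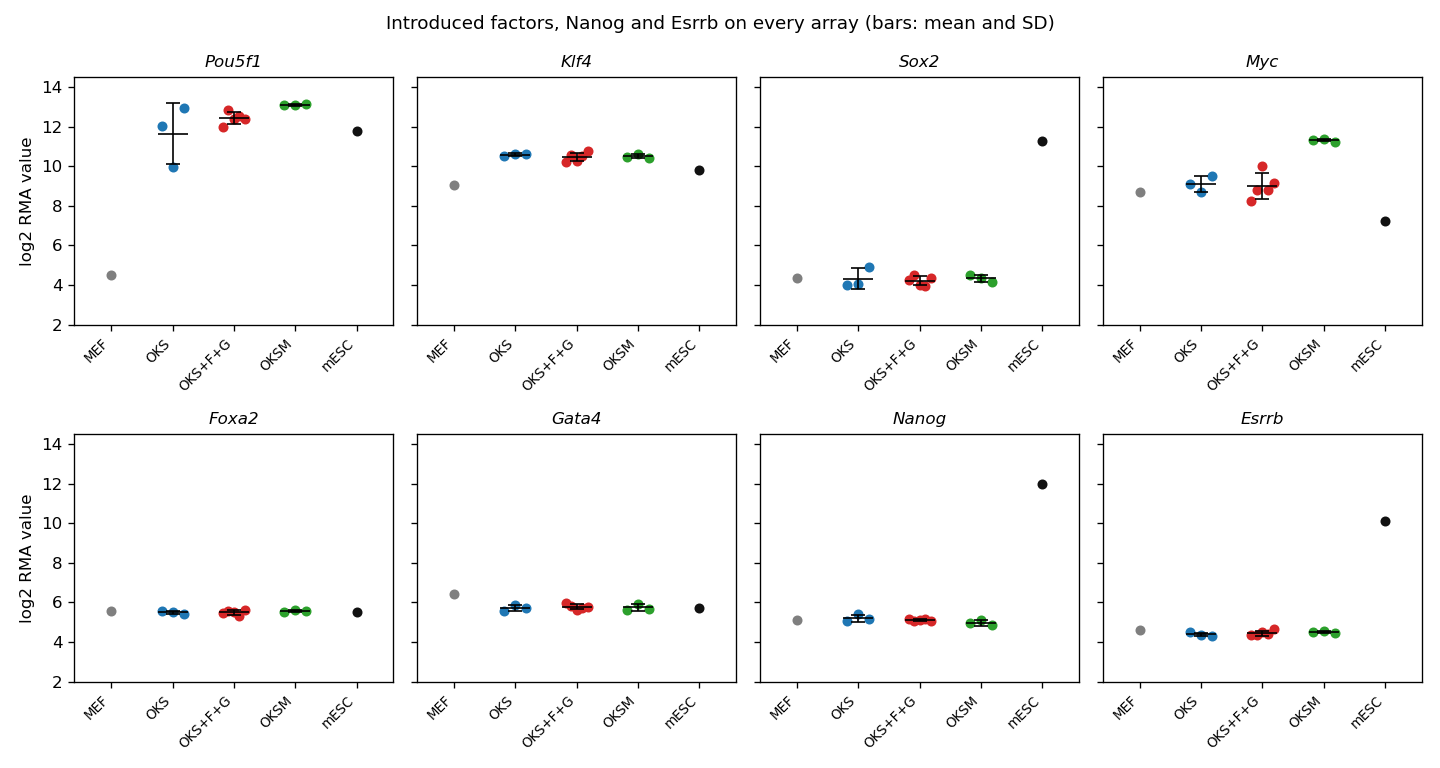
Deposited log2 RMA value (y axis) of the 6 introduced factors, Nanog and Esrrb on each array, with arrays grouped on the x axis as MEF, OKS, OKS+F+G, OKSM and mESC; points are arrays and bars the mean and SD of the clones. Pou5f1 lay at 9.95 or above in every clone and Myc was highest in the OKSM clones, while Sox2, Nanog and Esrrb were high on the mESC array alone.

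The stem cell and fibroblast arrays set the range in which the clones were placed. Of the genes measured, 713 were at least 2 (log2) higher in mESC and 1068 at least 2 higher in MEF. Among the largest differences on the mESC side, Dppa5a was higher by 8.12, Tdgf1, a Nodal co-receptor, by 7.85, Pou5f1 by 7.31, Sox2 by 6.96, Nanog by 6.86, Nr0b1 by 6.60, Utf1 by 6.52 and Dnmt3l, a cofactor of de novo DNA methylation, by 6.12. Bex1 and Lncenc1 were higher by 6.88 and 6.77. On the MEF side, the matrix genes Dcn, Lum, Aspn and Lox gave differences of -8.46, -8.44, -7.97 and -8.14. The matrix protease Mmp3 gave -8.62, and the secreted or inflammatory genes Lcn2, Saa3, Lyz2, Ccl3 and Cxcl5 gave -8.69, -8.37, -8.29, -7.81 and -7.71. Lyz2 and Ccl3 are abundant in macrophages. With 1 array on each side, these differences have no replicate check, and for all 20 the lower array was under 5.68, the level of the dimmest 25% of genes, so they are lower bounds.

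Against all 11 clones, the mESC array was at least 1 (log2) above the highest clone for 467 genes and below the lowest clone for 360. Among the widest gaps above the clones were those of the pluripotency genes Dppa5a (at least 8.21), Nanog (6.59), Sox2 (6.38), Dnmt3l (6.10) and Esrrb (5.47), all lower bounds in no order, since the highest clone was under 5.68. Nanog was 5.20 ± 0.18 (SD, n = 3), 5.11 ± 0.05 (SD, n = 5) and 4.97 ± 0.15 (SD, n = 3) in OKS, OKS+F+G and OKSM clones, 5.12 in MEF and 11.99 in mESC. Among the widest gaps below the clones were those of Msln (4.23), which encodes mesothelin, Osmr (3.99), the oncostatin M receptor, Anxa8 (3.69), Vat1l (3.63) and Cd44 (3.61), the hyaluronan receptor, with lower bounds for Osmr, Vat1l and Cd44. The MEF array was above every clone for 607 genes and below every clone for 160. Ccl3 (8.08), Adgre1 (6.53), Wfdc17 (6.51), Lyz2 (6.22) and Clec4n (6.18), genes expressed in macrophages, were among those with the widest gaps above, all but Lyz2 as lower bounds. Pou5f1 (5.47), Msln (4.79), Podxl (3.96), Vat1l (3.60) and Ly6g (3.05) were among those with the widest gaps below, all lower bounds, since MEF was under 5.68. These single arrays were not tested against the clones.

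Surface and matrix markers varied between clones. Thy1, a fibroblast surface marker, was 6.89 ± 1.66 (SD, n = 3) in OKS, where clone 3 was at 8.80, 6.17 ± 0.21 (SD, n = 5) in OKS+F+G and 6.48 ± 0.44 (SD, n = 3) in OKSM clones, against 10.40 in MEF and 6.80 in mESC. Cdh1, which encodes E-cadherin, ranged from 6.09 to 10.17 over the clones, with 5.72 in MEF and 10.43 in mESC. Col1a1, the main chain of type I collagen, was 12.06 ± 0.74, 12.20 ± 0.58 and 6.54 ± 0.11 in the OKS, OKS+F+G and OKSM clones, with 12.60 in MEF and 6.70 in mESC.

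The next comparison asked how far each set of factors had moved the clones from fibroblast towards stem cell expression. On the scale from 0 (MEF) to 1 (mESC), OKSM clones were at 0.727 ± 0.032 (SD, n = 3), OKS+F+G clones at 0.461 ± 0.028 (SD, n = 5) and OKS clones at 0.464 ± 0.076 (SD, n = 3). Of the 713 mESC-high genes, the OKSM mean lay within 25% of the MEF to mESC distance from the mESC value for 241, against 39 for OKS+F+G and 36 for OKS. Of the 1068 MEF-high genes, the mean lay that near the mESC value for 704 in OKSM, 373 in OKS+F+G and 383 in OKS. The mean of the pluripotency network list was 6.63 ± 0.15 in OKSM, 5.61 ± 0.10 in OKS+F+G and 5.43 ± 0.22 in OKS clones, against 9.68 in mESC and 5.01 in MEF. The mean of the fibroblast and mesenchyme list was 6.77 ± 0.26, 8.75 ± 0.28 and 8.87 ± 0.37 in the same order, against 6.17 in mESC and 10.70 in MEF.

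Between OKS+F+G and OKSM clones, the position, the correlations with mESC (0.778 ± 0.017 and 0.874 ± 0.004) and with MEF (0.824 ± 0.013 and 0.733 ± 0.019), and the means of the pluripotency network, late and naive pluripotency, fibroblast, and primitive and visceral endoderm lists all gave an exact p = 0.0357, the smallest that 3 against 5 clones allow. For late and naive pluripotency the difference in means of -0.63 became -0.16 with an exact p = 0.179 when the median over the list was taken. The epithelial list gave an exact p = 0.25 and the definitive endoderm and liver list 0.821. OKSM and OKS clones did not overlap in position, but 3 against 3 clones cannot give less than an exact p = 0.1. OKS+F+G and OKS clones gave exact p values of 0.929 for the position, 0.607 for the correlation with mESC, 0.929 for that with MEF, 0.179 for pluripotency network, 0.321 for late and naive pluripotency, 0.607 for fibroblast, 0.143 for epithelial, 0.714 for definitive endoderm and liver and 0.679 for primitive and visceral endoderm genes. After adjustment over 27 comparisons the smallest exact p was 0.138. With the smallest p values that these group sizes allow, no comparison could reach an adjusted p under 0.05, so this outcome was fixed beforehand. Omission of any of the 8 clones left every p between OKS+F+G and OKSM at an exact 0.0571 or above, which the smaller groups force, and OKS clone 3 had the lowest position of all clones, 0.377.

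**Figure D2:**
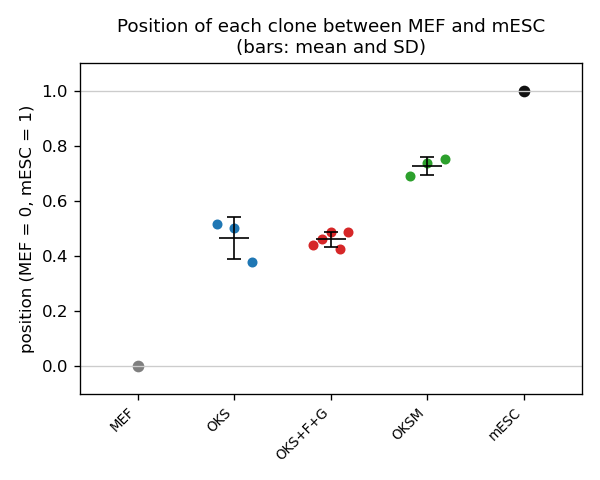
Position of each clone between the MEF array (0) and the mESC array (1), a fitted share without unit (y axis), by factor set (x axis); points are clones and bars the mean and SD. The OKSM clones averaged 0.727, apart from OKS+F+G (0.461) and OKS (0.464), and OKS clone 3 was lowest at 0.377.

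**Figure D3:**
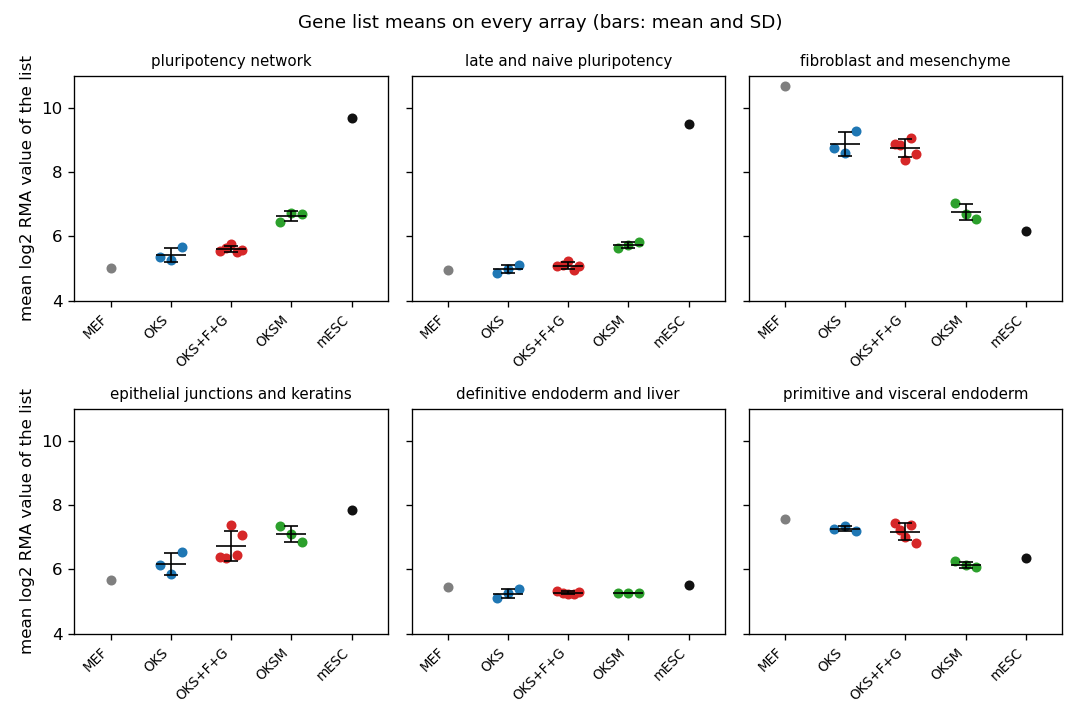
Mean log2 RMA value (y axis) of 6 gene lists on each array, with arrays grouped on the x axis as MEF, OKS, OKS+F+G, OKSM and mESC; points are arrays and bars the mean and SD of the clones. OKSM clones averaged 6.63 for the pluripotency network and 6.77 for fibroblast genes, while definitive endoderm and liver genes averaged 5.24, 5.27 and 5.27 in the OKS, OKS+F+G and OKSM clones.

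The central comparison asked what Foxa2 and Gata4 added to OKS, and 6 genes differed between OKS+F+G and OKS clones, 3 higher and 3 lower. Shox2, a homeobox gene of limb and heart, rose from 4.20 ± 0.08 (SD, n = 3) to 5.24 ± 0.12 (SD, n = 5), a difference of 1.03 (log2, SE 0.09, limma adjusted p = 0.00582). Its OKS values lay at percentiles 2.41 to 3.56 of the genes on their arrays, near the floor, and its OKS+F+G mean was also under 5.68, so the size of the difference is uncertain. Flvcr2, a transmembrane transporter, rose by 2.25 (SE 0.30, limma adjusted p = 0.046), and the histone gene H2bc4 by 1.55 (SE 0.21, limma adjusted p = 0.046). Histone gene copies are alike in sequence, so the H2bc4 probe set may not separate them. Adgrl3, an adhesion receptor, fell by 1.61 (SE 0.19, limma adjusted p = 0.029), a lower bound, with OKS+F+G values at percentiles 1.59 to 6.53. Prrx2, a homeobox gene of mesenchyme, fell by 1.33 (SE 0.16, limma adjusted p = 0.029), and Csf1, the macrophage growth factor, fell by 1.20 (SE 0.16, limma adjusted p = 0.046). Prrx2 was 8.73 ± 0.17 in OKS, 7.40 ± 0.15 in OKS+F+G and 5.49 ± 0.34 in OKSM clones, with 8.89 in MEF.

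**Figure D4:**
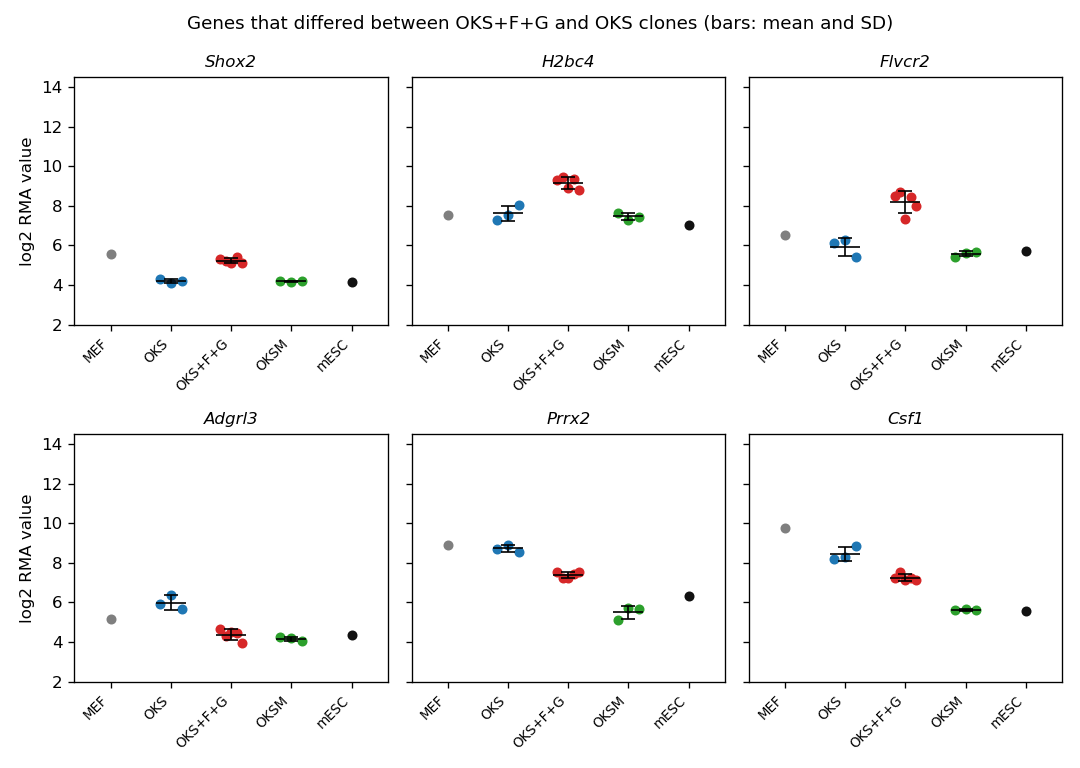
Deposited log2 RMA value (y axis) on each array of the 6 genes called between OKS+F+G and OKS clones, with arrays grouped on the x axis as MEF, OKS, OKS+F+G, OKSM and mESC; points are arrays and bars the mean and SD of the clones. Shox2, H2bc4 and Flvcr2 were higher in all OKS+F+G than in all OKS clones, and Adgrl3, Prrx2 and Csf1 lower.

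The differences kept about their size whichever of the 8 clones was left out: 0.99 to 1.07 for Shox2, 1.99 to 2.47 for Flvcr2, 1.38 to 1.76 for H2bc4, -1.78 to -1.41 for Adgrl3, -1.41 to -1.24 for Prrx2 and -1.33 to -0.99 for Csf1. Their sign could not change, since the groups did not overlap for any of the 6 genes. The calls depended on single clones. Without OKS clone 3 the count became 1572 (772 higher, 800 lower), among them all 6 genes, and without OKS+F+G clone 6 it was 28. Without OKS clone 1 or OKS+F+G clone 2 or 5 it was 1, and without OKS clone 2 it was 0 in limma. Omission of OKS+F+G clone 1 or 3 left 5 calls, 3 of them from the 6. Of the 1572 calls without OKS clone 3, 145 (9.22%) were on chromosome 19, which holds 3.39% of the genes, and 135 of these were lower in OKS+F+G. Over the 8 fits that each left out 1 clone, Shox2 lost its call in 1, Adgrl3 in 4, Flvcr2 and Prrx2 in 5, and H2bc4 and Csf1 in 6. The count was 0 without the dimmest genes, and with arrays centred on their medians it was 4, 1 higher and 3 lower, and after a further quantile normalization 3, 1 higher and 2 lower. With only these groups in the fit it was 2, with a trended and robust eBayes 3, with OKS clones 1 and 2 averaged 1, and with array weights 2715 (1359 higher, 1356 lower), among them all 6 genes. At an unadjusted p under 0.05, 1440 genes passed where chance gives 743.8.

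No list had a member past the threshold over all genes between OKS+F+G and OKS clones, and 5 lists shifted as a whole in camera. Of 28 epithelial junction and keratin genes, 1 was higher adjusted over the list alone, Dsp, the desmosome protein desmoplakin, at 1.53 (SE 0.35). The list's median difference was 0.44 (camera adjusted p = 0.0015, but adjusted p = 0.897 with an estimated correlation). In its mean per clone, OKS+F+G clones 3 and 6 were highest (7.37 and 7.06). OKS+F+G clones 1, 2 and 5 (6.38, 6.36 and 6.45) lay below OKS clone 3 (6.53) and above OKS clones 1 and 2 (6.15 and 5.85). Perp and Cldn3 were at 1.23 and 1.00 and Cdh3 at -1.42 or lower, none past the threshold. Of 18 genes of p53, senescence and cell cycle arrest, 4 were higher adjusted over the list alone: Igfbp7 at 1.01, Perp at 1.23, Btg2 at 0.77 and Trp53inp1 at 0.94. Their median was 0.41 (camera adjusted p = 1.03e-04, adjusted p = 0.436 with an estimated correlation). Of 20 imprinted genes, Zim1 at 2.22 or more, its OKS mean being under 5.68, was higher adjusted over the list alone, and the median was 0.36 (camera adjusted p = 0.0369, adjusted p = 0.436 with an estimated correlation). Meg3, Peg3 and Nnat did not pass.

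Of 27 genes of ribosome biogenesis and Myc targets, none passed adjusted over the list alone, and the median was -0.39 (camera adjusted p = 3.87e-05, adjusted p = 0.897 with an estimated correlation). Cad, of pyrimidine synthesis, was at -0.64, Nop2 at -0.58, Rcl1 at -0.78 and Mybbp1a at -0.49. Of 28 cell cycle genes none passed either, with a median of -0.29 (camera adjusted p = 0.0184, adjusted p = 0.897 with an estimated correlation). Without OKS clone 1 the camera adjusted p became 0.114 for the ribosome list, 0.114 for imprinted and 0.418 for cell cycle genes. The cell cycle list also lost its call without OKS clone 2 (adjusted p = 0.147), OKS+F+G clone 1 (0.19) or OKS+F+G clone 5 (0.0811), and after quantile normalization (0.0563). The imprinted list lost it without OKS clone 3 (adjusted p = 0.155) and OKS+F+G clones 1 (0.0512), 2 (0.0718) and 5 (0.15).

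The endoderm lists, which include targets and partners of Foxa2 and Gata4, did not pass between OKS+F+G and OKS clones. Of the 30 genes in the definitive endoderm and liver list only 15 were measured, so nothing is said of the others. Over the 15 measured genes, the median was -0.05 and the mean 0.03, with the test on the negative side (camera adjusted p = 0.632). Their mean value was 5.24 in OKS and 5.27 in OKS+F+G clones, 5.51 in mESC and 5.45 in MEF. All of these means are under 5.68, so dim signal limits what this list can show. Rbp4, the retinol carrier, was at -0.34 and Ahsg, a liver-secreted protein, at 0.41, both with group means under 5.68, so that their sizes are uncertain. Over 23 genes of primitive and visceral endoderm the median was -0.05 (camera adjusted p = 0.476), with Thbd at -2.34 and the endocytic receptor Lrp2 at 2.08. Among 17 trophoblast genes (camera adjusted p = 0.542), Gata2 at 1.74 (SE 0.35) was higher adjusted over the list alone. Among 20 mesoderm and heart genes (camera adjusted p = 0.937), Tbx5 at 1.05 or more was higher and Hand2 at -0.40 lower adjusted over the list alone, with a mean of 0.09 and a median of -0.02. Among 14 neural genes (camera adjusted p = 0.848), Gap43 was lower adjusted over the list alone. Camera adjusted p was 0.846 for the pluripotency network, where L1td1 was at 1.84, 0.937 for late and naive pluripotency, 0.962 for primed epiblast (median -0.01, mean 0.06), 0.38 for fibroblast, where Dcn was at 1.76, 0.393 for blood and endothelium, 0.349 for germ cell, 0.937 for TGF-beta and BMP, 0.846 for Dnmt, Tet and Polycomb, and 0.365 for interferon genes. The 3 sex chromosome markers (camera adjusted p = 0.937) had a median of -0.22 and a mean of 0.89, and Xist, high in OKS clone 3 alone of its group, was higher adjusted over the list alone. The 6 introduced factors had a median of -0.06 and a mean of 0.08 (camera adjusted p = 0.962).

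The OKSM clones were compared with OKS clones to ask what Myc added, and 3464 genes (23.3% of those tested) differed, 2020 higher and 1444 lower. By at least 1 (log2), 637 were higher and 776 lower. Among genes that fell, Lox, the collagen cross-linking enzyme, fell by 6.22 (SE 0.39, limma adjusted p = 2.1e-05), from 10.88 ± 0.54 (SD, n = 3) to 4.66 ± 0.15 (SD, n = 3). The cadherin Cdh11, the proteoglycans Bgn and Vcan, the actin-binding Tagln, the protease inhibitor Timp2, Col1a1 and Sema3c gave differences of -5.89, -5.88, -5.64, -5.68, -5.53, -5.52 and -5.40. The growth factor binding proteins Igfbp4 and Igfbp7 gave -5.76 and -4.90. Among genes that rose, Nr0b1, a nuclear receptor of stem cells, was higher by 5.59 (SE 0.68, limma adjusted p = 0.000596), Tdgf1 by 4.86 (SE 0.46), the transcription factor Zic2 by 4.40 (SE 0.58) and the keratin Krt19 by 4.71 (SE 0.95). Tdgf1 went from 4.55 ± 0.18 to 9.40 ± 1.20, with 12.40 in mESC. The amino acid transporters Slc38a5 and Slc6a15 rose by 5.65 and 4.82, Tmem45b by 4.39, Fetub by 3.96, Laptm5 by 3.85 and Cyp2b23 by 5.58, and cytochrome P450 paralogs may share the last probe set. In the limma count, omission of OKSM clone 2, OKS clone 2 or OKSM clone 3 lowered the number to 2105, 2233 or 2273, and array weights raised it to 6207. For 12 of the 20 largest differences, Lox, Bgn, Tdgf1 and Nr0b1 among them, the lower group's mean was under 5.68, so these are lower bounds. The Xist and chromosome 19 values of OKS clones 1 and 2 stand beside these differences.

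Of 35 fibroblast and mesenchyme genes, 17 fell, none rose and 18 did not pass, and 22 were lower adjusted over the list alone. The list's median was -1.73 (camera adjusted p = 8.43e-13, adjusted p = 0.0807 with an estimated correlation). Col3a1 fell by 4.04 and Dcn fell by 2.73. Of 23 TGF-beta and BMP targets, 11 fell and 12 did not pass, 11 lower adjusted over the list alone, with a median of -1.41 (camera adjusted p = 1.45e-07, adjusted p = 0.0807 with an estimated correlation). Inhba, an activin subunit, fell by 3.59 or more, its OKSM mean being under 5.68, and Ccn2, a matricellular protein, fell by 2.70. Of 23 primitive and visceral endoderm genes, 6 fell and 17 did not pass, 7 lower adjusted over the list alone, with a median of -0.85 (camera adjusted p = 0.000116, adjusted p = 0.0807 with an estimated correlation). Dab2, an endocytic adaptor, fell by 2.46.

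Of 30 pluripotency network genes, 13 rose, 1 fell and 16 did not pass, and 14 were higher and 1 lower adjusted over the list alone. The median was 0.51 (camera adjusted p = 0.000655, adjusted p = 0.115 with an estimated correlation). L1td1 rose by 3.28, Fbxo15 by at least 3.68, Gdf3 by at least 2.53 and Nr5a2 by at least 0.97, the OKS means of the last 3 being under 5.68. Dppa2, under that level in both groups, did not pass. Of 19 late and naive pluripotency genes, 6 rose and 1 fell, before and after adjustment over the list alone (camera adjusted p = 0.0706). Of 14 primed epiblast genes, 6 rose and 1 fell, 6 and 2 adjusted over the list alone (camera adjusted p = 0.0461, adjusted p = 0.288 with an estimated correlation). The camera call of this list was lost without OKS clone 1 (adjusted p = 0.0666), OKS clone 3 (0.168) or the dimmest genes (0.796). Zic5 rose by 0.87 on its brighter probe set and was 3.70 higher on its other one, which the test did not use. Of 27 genes of ribosome biogenesis and Myc targets, 13 rose and none fell, 19 adjusted over the list alone, with a median of 0.85 (camera adjusted p = 5.27e-06, adjusted p = 0.557 with an estimated correlation). Cad rose by 1.15 and Mybbp1a by 0.75.

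Of 28 epithelial genes, 5 rose, as many adjusted over the list alone (camera adjusted p = 0.0116, adjusted p = 0.621 with an estimated correlation), and this call was lost without OKSM clone 1 (adjusted p = 0.0837). Dsp rose by 1.34 and Perp by 1.96. Of 21 Dnmt, Tet and Polycomb regulators, 6 rose, 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0108, adjusted p = 0.127 with an estimated correlation), and the call was lost without OKS clone 3 (adjusted p = 0.065). Jarid2 rose by 1.11, Tet2 by 0.96 and the histone demethylase Kdm1a by 0.45. Among imprinted genes, 3 rose and 6 fell (camera adjusted p = 0.0706), with Meg3 falling by 4.80 (SE 0.33). Myc was the 1 introduced factor that rose (camera adjusted p = 0.549). Among p53 and arrest genes 5 rose and 3 fell, with a median of 0.13 and a mean of -0.07 (camera adjusted p = 0.842), Trp53inp1 rising from 8.66 ± 0.47 to 10.16 ± 0.21 and Igfbp7 falling. The counts of rising and falling genes were 4 and 0 for cell cycle (camera adjusted p = 0.108), 3 and 0 for trophoblast (0.363), 4 and 3 for mesoderm (0.651), 1 and 2 for neural (0.442), 2 and 1 for blood and endothelium (0.549), 1 and 1 for interferon (0.638), and 1 and 0 for definitive endoderm and liver genes (0.724), the 1 being Ahsg at 1.35 or more. In this last list the median of 0.08 and the test differed in sign. No germ cell gene (camera adjusted p = 0.975) or sex chromosome marker (0.724) passed over all genes, and the latter had a median of -0.17 and a mean of 0.78.

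The OKS+F+G clones were compared with OKSM clones, the standard cocktail of 4 factors, and 4766 genes (32.0%) differed, 2108 higher in OKS+F+G and 2658 lower. By at least 1 (log2), 1040 were higher and 652 lower. Among the largest, Igfbp4 was higher in OKS+F+G by 6.35 (SE 0.50, limma adjusted p = 4.73e-05), Igfbp7 by 5.91 (SE 0.24), Lox by 5.87 (SE 0.35) and Col1a1 by 5.66 (SE 0.36). The matrix and actin genes Tagln, Bgn and Timp2 were higher by 5.93, 5.37 and 5.29, the imprinted genes Meg3 and Igf2 by 5.67 and 5.47, and the uroplakin Upk3b by 5.24. Lower in OKS+F+G were Tdgf1 at -5.04 (SE 0.41), Nr0b1 at -4.58 (SE 0.61) and Otx2, a transcription factor of the epiblast and forebrain, at -3.81 (SE 0.38). Slc38a5 and Slc6a15 were at -4.90 and -4.65, Cyp2b23 and Cyp2s1 at -5.59 and -4.54, Tmem45b at -4.29, Clec2i at -3.88 and the lipid phosphatase Inpp5d at -3.72. Myc was at -2.32. In limma, omission of OKSM clone 2 lowered the count to 3092. For 11 of the 20 largest differences, again with Lox, Bgn, Tdgf1 and Nr0b1, the lower group's mean was under 5.68, so these are lower bounds.

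In list tests, 20 of 35 fibroblast and mesenchyme genes were higher in OKS+F+G than in OKSM clones, 1 lower and 14 not past the threshold, 21 and 1 adjusted over the list alone (median 1.57, camera adjusted p = 4.33e-10, adjusted p = 0.111 with an estimated correlation). Dcn was higher by 4.49 and Col3a1 by 3.35, and Snai1 was lower at -0.73. Of 23 TGF-beta and BMP targets, 13 were higher, 15 adjusted over the list alone (median 1.20, camera adjusted p = 1.63e-07, adjusted p = 0.111 with an estimated correlation), among them Ccn2 at 3.69 and Inhba at 2.58 or more. Of 23 primitive and visceral endoderm genes, 9 were higher, 10 adjusted over the list alone (median 0.88, camera adjusted p = 0.00242, adjusted p = 0.111 with an estimated correlation), with Lrp2 at 3.78 or more and Dab2 at 1.78. Of 20 imprinted genes, 9 were higher and 3 lower, 10 and 3 adjusted over the list alone (median 0.73, camera adjusted p = 0.0102, adjusted p = 0.127 with an estimated correlation), with Zim1 at 2.46 or more. The OKSM means of Inhba, Lrp2 and Zim1 were under 5.68. Of 27 ribosome biogenesis genes and Myc targets, 23 were lower, as many adjusted over the list alone (median -1.18, camera adjusted p = 3.21e-09, adjusted p = 0.378 with an estimated correlation), with Cad at -1.79, Rcl1 at -1.42, Mybbp1a at -1.24 and Nop2 at -1.19. Of 28 cell cycle genes, 4 were lower, 2 adjusted over the list alone (median -0.74, camera adjusted p = 0.00242, adjusted p = 0.68 with an estimated correlation).

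Among the 30 pluripotency network genes, 12 were lower in OKS+F+G than in OKSM clones and 1 higher, with the same numbers adjusted over the list alone (median -0.42, camera adjusted p = 0.00236, adjusted p = 0.127 with an estimated correlation). Gdf3 was at -1.89 and Nr5a2 at -1.15 or lower, its OKS+F+G mean being under 5.68. Of 14 primed epiblast genes, 7 were lower and 2 higher, with the same numbers over the list alone (camera adjusted p = 0.0415, adjusted p = 0.29 with an estimated correlation), Zic2 at -3.71 and Zic5 at -0.66 on its brighter probe set and -3.65 on the other, which the test did not use. This call was lost without OKS+F+G clone 3 (adjusted p = 0.0917) or the dimmest genes (0.846). Of 21 Dnmt, Tet and Polycomb regulators, 8 were lower and 1 higher, 10 and 1 adjusted over the list alone (camera adjusted p = 0.0145, adjusted p = 0.137 with an estimated correlation), with Jarid2 at -0.81. The other lists did not pass. Counts of higher and lower genes were 1 and 6 for late and naive pluripotency (camera adjusted p = 0.0952), 0 and 5 for epithelial (0.417), 0 and 1 for definitive endoderm and liver (0.9), 1 and 3 for trophoblast (0.452), where Gata2 was at 2.87 or more and Peg10 at -2.10, 6 and 5 for mesoderm and heart (0.729), 1 and 0 for neural (0.417), 0 and 3 for blood and endothelium (0.215), 5 and 2 for p53 and arrest (0.268) and 1 and 0 for interferon genes (0.221). The mesoderm list had a median of -0.04 and a mean of 0.38, with Tbx5 at 1.19 or more, Mef2c at 1.15 and Mesp1, under 5.68 in both groups, at -0.44. Among introduced factors only Myc passed (camera adjusted p = 0.452), and no germ cell (0.452) or sex chromosome gene (0.729) did.

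Finally, OKS+F+G clones were set against the mean of both sets of clones without Foxa2 and Gata4, and 2034 genes (13.7%) differed, 949 higher and 1085 lower. By at least 1 (log2), 331 were higher and 89 lower. With arrays centred on their medians the split was 801 higher and 1411 lower. A gene can pass here through its difference from one of the groups alone. Igfbp7 was higher by 3.46 (SE 0.20, limma adjusted p = 4.19e-05), Aldh1a1, which makes retinoic acid, by 2.65 (SE 0.24), Flvcr2 by 2.43 (SE 0.25) and Gata2 by 2.31 (SE 0.29). Flvcr2 was 8.19 ± 0.55 (SD, n = 5) in OKS+F+G, 5.94 ± 0.45 (SD, n = 3) in OKS and 5.57 ± 0.12 (SD, n = 3) in OKSM clones, and Gata2 8.32 ± 0.52, 6.58 ± 0.70 and 5.45 ± 0.30. Tspan2, Pygl, Prelp, Zim1 and Slc30a2 were higher by 2.53, 2.52, 2.49, 2.34 and 2.27, and Akr1cl went from 3.84 ± 0.14 in OKS and 3.94 ± 0.17 in OKSM clones to 6.39 ± 1.01. Emb, which encodes embigin, was lower at -2.65 (SE 0.37), with 5.59 ± 0.70 in OKS+F+G against 7.90 ± 0.60 in OKS and 8.59 ± 0.69 in OKSM clones, and Thbd was at -1.69. Mir18, S100a16, Fkbp5, Nme4, Smpdl3b, Utp14a, Pus7 and Slc1a5 were lower at -1.40, -1.40, -1.25, -1.25, -1.14, -1.10, -1.01 and -0.90. For 7 of the 20, Akr1cl, Zim1, Slc30a2, Emb, Mir18, Nme4 and Smpdl3b, the lower side was under 5.68, so these are lower bounds, except that for Mir18 both sides were and its size is uncertain. A second, dimmer probe set of Pus7, which the test did not use, gave -0.47 against OKS and -0.60 against OKSM, where the tested one gave -0.83 and -1.19.

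Against that mean, 12 of 35 fibroblast genes were higher, 15 with 1 lower adjusted over the list alone (camera adjusted p = 3.26e-07, adjusted p = 0.247 with an estimated correlation). Of 23 TGF-beta and BMP targets 6 were higher, 9 over the list alone (camera adjusted p = 9.68e-06, adjusted p = 0.247 with an estimated correlation). Of 20 imprinted genes, 6 were higher and 2 lower, 10 and 2 over the list alone (camera adjusted p = 0.00595, adjusted p = 0.247 with an estimated correlation). Of 18 p53 and arrest genes, 4 were higher, 4 with 1 lower over the list alone (camera adjusted p = 0.01, adjusted p = 0.279 with an estimated correlation). Of 23 primitive and visceral endoderm genes, 5 were higher and 1 lower, before and after adjustment over the list alone (camera adjusted p = 0.0363, adjusted p = 0.249 with an estimated correlation). This call was lost without OKS clone 1 (adjusted p = 0.0536) or OKS+F+G clone 1 (0.0786). The list averaged 7.17 in OKS+F+G, 7.27 in OKS and 6.15 in OKSM clones, with 7.57 in MEF and 6.37 in mESC. OKS+F+G clones were thus on average above OKSM but not above OKS clones. The same held for the fibroblast list, at 8.75, 8.87 and 6.77 in OKS+F+G, OKS and OKSM clones. Ribosome biogenesis and Myc targets were lower as a list, with 18 of 27 lower and 23 over the list alone (camera adjusted p = 2.49e-10, adjusted p = 0.279 with an estimated correlation). Cell cycle genes were lower as a list with no member past the threshold (camera adjusted p = 0.000821, adjusted p = 0.654 with an estimated correlation). The pluripotency network was lower too, with 8 of 30 lower and 9 over the list alone (camera adjusted p = 0.00749, adjusted p = 0.249 with an estimated correlation). Its mean was 5.61 in OKS+F+G, 5.43 in OKS and 6.63 in OKSM clones, so only the OKSM clones averaged above OKS+F+G. The other 13 lists did not pass. Among them, the median and mean differed in sign for definitive endoderm and liver (-0.07 and 0.01), trophoblast (-0.06 and 0.07), mesoderm and heart (-0.04 and 0.24) and sex chromosome markers (-0.09 and 0.50). In limma the number of genes became 3848 without OKS clone 3, 1172 or 1326 without OKS clone 1 or 2, 1136, 1040 or 933 without OKS+F+G clone 1, 2 or 5, and 1038 or 1200 without OKSM clone 2 or 3. With array weights it was 5223, and with OKS clones 1 and 2 averaged 1242.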

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

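Of the tests in this part, those for a wrong label, for splits with the OKSM clones kept, for silenced factors, for probe sets that miss the introduced sequences and for left-over MEF cells were chosen after the results were seen. Among 137 measures tested in the 5 OKS+F+G clones, 8 had 1 clone far from the others by Dixon's criterion. Chance gives about 1 in 20 groups, so these 8 are near the number that chance gives. Clone 6 was lowest for the neural gene Nes (5.12, next 6.78) and highest for Ddx4 (3.62, next 3.48) and for Ddx58 (9.21, next 8.10), a sensor of viral RNA. Clone 1 was lowest for Nop2 (7.92, next 8.41) and highest for Dppa2 (4.02, next 3.78). Clone 2 was highest for Ahsg (5.42, next 4.78), clone 3 for Tmem45b (4.59, next 3.93) and clone 5 for Zic2 (7.84, next 5.75). Ddx4 and Dppa2 lie near the floor of the arrays, and the Tmem45b and Ahsg values and that of Nes in clone 6 were under 5.68.

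Other groupings of the same clones were fitted to ask whether chance can be excluded. For OKS+F+G against OKS, 5 of the 56 splits gave at least the 6 genes of the real one, so chance is not excluded. The highest other split gave 547 genes, with OKS clone 3 and OKS+F+G clones 3 and 6 on one side, which points to a structure of the samples, though this split was picked as the highest and what it follows was not tested. For OKS+F+G against OKSM, 1 of 56 splits, the real one with 4766 genes, was as large, a share under 0.05, and the highest other gave 579. For OKS+F+G against the mean of the other groups, 1 of 100 labellings of all 11 clones was as large as the real one (2034 genes, highest other 1781), also a share under 0.05. Both shares take the clones as independent, so they cannot exclude that clones of a group share an origin. With the OKSM clones kept and only OKS and OKS+F+G clones split, 11 of 56 splits gave at least 2034 genes (highest other 3664, again with OKS clone 3 and OKS+F+G clones 3 and 6 on one side), so chance is not excluded for the part that sets OKS+F+G apart from OKS. For OKSM against OKS, 1 of 10 splits was as large (3464 genes, highest other 0), and 10 splits are too few for a share under 0.05.

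OKS clone 3 stood apart from clones 1 and 2, with 610 genes at least 2 (log2) from their mean. Those genes lay among the MEF and mESC genes more often than others, with an odds ratio of 4.21 (95% interval 3.51 to 5.03). An array fault was taken to give a ratio near 1, but the other genes were not matched on expression range. Genes with a wide range can enter both sets, so the ratio does not decide whether the array was poor. A wrong label on an OKS+F+G clone cannot be told apart from an unusual pair of clones 1 and 2. Against it, the mean correlation of clone 3 with OKS+F+G clones was 0.930 (OKS 1 0.946, OKS 2 0.933), below the lowest of 0.949 among these by more than 2 of their SDs (0.00640), a test first read alone. For it, clone 3 correlated less with OKS 1 and 2 (0.891 and 0.873). Over the 1572 genes called without clone 3, its median position from OKS 1 and 2 (0) to OKS+F+G (1) was 1.24. Those genes were picked as differing between OKS 1 and 2 and the OKS+F+G clones. An unusual pair predicts such a position too, so it does not decide the label. No biological explanation was tested.

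Sox2, Foxa2 and Gata4 stood near or below the MEF level in the clones that received them. Pou5f1 exceeded MEF by at least 5.47 (log2) in every clone while Nanog and Esrrb stayed within 0.289 of MEF. This would argue against silencing of all introduced factors if the endogenous Pou5f1 gene was off. The Pou5f1 probe set may read both transcripts, and in OKSM clones Nr0b1 (10.10) and Tdgf1 (9.40) stood far above MEF (4.25 and 4.55). The source of the Pou5f1 signal was not tested, so silencing of all factors is not decided. Probe sets that do not read the introduced sequences cannot be told apart from loss of these 3 factors: the largest excess over MEF was 0.575 (Sox2 in OKS 3), which both predict, and the sequences of the probes and vectors were not used here. It therefore stays open whether the OKS+F+G clones still expressed Foxa2 and Gata4 when RNA was taken, and no biological explanation was tested.

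Part of the fibroblast list stayed high in OKS and OKS+F+G clones, while 6 to 10 of 24 genes were under 0.1 of the MEF excess. Left-over MEF cells would put every such gene at about one share of its MEF level. Over 24 genes of the fixed list, the share of the MEF excess over OKSM clones was under 0.1 at the 10th percentile and over 0.3 at the 90th in 8 of 8 clones, with Lum at 0.0173 or less and Postn at 0.0384 or less while Col1a1 ran from 0.371 to 1.12, which argues against them as the whole cause. The bounds were set after the shares were seen, and an earlier form over 349 MEF-high genes met its bounds in 7 of 8 clones. A partial loss of the fibroblast program in the clones themselves may account for the pattern, as a hypothesis, and a small admixture stays open.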

How the results depend on the processing

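Averaging OKS clones 1 and 2 and leaving out X-linked genes were chosen after seeing the data, and the other alternatives before. Where a value below moved, the cause was not tested unless fewer samples or genes show it. Over all alternatives, named genes gave 7163 values, of which 6768 kept their side of the threshold, 223 became weaker, 172 stronger and 0 reversed. Gene lists gave 1248 values, with 1123, 68, 57 and 0. Reversed means a changed sign in a gene called in either fit, or in a list called in both. A sign change in a gene or list called in neither fit was counted as kept, so these numbers do not show that every direction held. The number of genes between OKS+F+G and OKS clones, 6, became 2 with those groups alone in the fit, 3 with a trended and robust eBayes, 3 after quantile normalization, 0 without the dimmest genes (1440 of all genes had an unadjusted p under 0.05 in limma), 2715 with array weights and 1 with OKS clones 1 and 2 averaged. Array weights gave 6207 genes for OKSM against OKS and 5223 for OKS+F+G against the mean, and averaging clones 1 and 2 gave 1242 for the latter. With a difference of at least 1 (log2) also required, 1413, 1692 and 420 genes remained for OKSM against OKS, OKS+F+G against OKSM, and OKS+F+G against the mean. Without X-linked genes the 4 counts were 6, 3369, 4629 and 1993.

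Clone numbers did not pair the samples: deviations of same-numbered clones correlated at -0.0681 to 0.179 between OKS and OKS+F+G, -0.22 to 0.168 between OKS and OKSM, and -0.0484 to -0.016 between OKS+F+G and OKSM. With clone number as a replicate block over clones 1 to 3, the counts were 0, 2516, 2859 and 232 for OKS+F+G against OKS, OKSM against OKS, OKS+F+G against OKSM and OKS+F+G against the mean, from fewer clones (limma, 1440 genes at an unadjusted p under 0.05 in the first without the block). Under the block the list calls of camera were lost for imprinted genes between OKS+F+G and OKS (adjusted p = 0.0763) and for primed epiblast genes between OKSM and OKS (0.0774) and between OKS+F+G and OKSM (0.0515).

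Of the list calls of camera (5, 8, 9 and 8), 0 were left in each contrast with an estimated correlation. Fry in one direction gave 0, 10, 14 and 11 lists and in either direction 0, 17, 18 and 13, but it does not compare a list with other genes. With OKS clones 1 and 2 averaged, the cell cycle list lost its call between OKS+F+G and OKS (camera adjusted p = 0.883).

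Leaving out 1 clone, genes past the limma threshold ran from 0 (without OKS 2; 1440 at an unadjusted p under 0.05 with all clones) to 1572 (without OKS 3) for OKS+F+G against OKS, 2105 to 4497 for OKSM against OKS, 3092 to 4858 for OKS+F+G against OKSM and 933 to 3848 for OKS+F+G against the mean, and list calls from 2 (without OKS 1; 3 without OKS+F+G 1 or 5) to 5 in the first. The other clones that moved a count by over 1.5 times stand beside the results. Per-clone differences of OKS+F+G from OKSM ran from -0.103 to -0.0921 for similarity to mESC, 0.0845 to 0.102 for similarity to MEF, -0.285 to -0.254 for position, -1.11 to -0.97 for the pluripotency network, -0.68 to -0.59 for late and naive pluripotency, 1.87 to 2.13 for fibroblast and 0.96 to 1.12 for primitive and visceral endoderm genes. Their exact p lay between 0.0571 and 0.0952, which the smaller groups force. The median over the late and naive list gave -0.16. At least 1 apart, 4792 genes separated mESC from MEF. At least 2 outside all clones were 220 genes for mESC and 277 for MEF. Quantile normalization gave a Pou5f1 mean of 13.06 in OKSM clones. Signal near the floor limits Sox2, Foxa2 and Gata4 in the clones and leaves a lower bound for Adgrl3 and an uncertain size for Shox2, and the number of arrays limits every comparison.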

Other observations

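Of the tests in this part, that of X-linked genes was written before its result was seen, and those of mesothelial genes, blood genes and whole chromosomes were chosen after. Msln, high in all clones and in neither reference, was 10.92 ± 0.24 (SD, n = 3) in OKS, 11.58 ± 0.78 (SD, n = 5) in OKS+F+G and 10.71 ± 0.13 (SD, n = 3) in OKSM clones, against 6.19 in mESC and 5.63 in MEF. Mesothelial expression in the 8 OKS and OKS+F+G clones may account for this, as a hypothesis. A list of 20 mesothelial genes, shortened after values were seen, had 19 measured, and its median excess over both references lay above the 99th percentile of random lists in 3 of 8 clones (OKS 1 and 2 and OKS+F+G 3). The percentile was 98.5 in OKS+F+G 2, 97.6 in OKS+F+G 1, 90.9 in OKS+F+G 6, 49.5 in OKS+F+G 5 and 11.2 in OKS 3. It was 2.16 to 3.18 in the OKSM clones, which were high in Msln as well. A mesothelial state shared by all clones is thus not shown.

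The MEF array carried blood genes. Over 17 measured genes of the blood and endothelium list, fixed before the data were examined, the median excess of MEF over every other array was 2.28 (log2), at percentile 100 of random lists matched on mean expression, and 9 genes were at least 1 above. Blood cells among the MEF cells may account for this, as a hypothesis. Cd53, Fcer1g and Ptprc, expressed in white blood cells, exceeded all arrays by at least 5.64, 5.32 and 3.66, the other arrays being under 5.68, while the endothelial genes Tek and Pecam1 gave -6.00 and -3.35 or lower. Of 26 measured genes of a macrophage list written after the values were seen, 23 were at least 1 above, with Lyz2 at 12.43, Ccl3 at 12.28 and Adgre1 at 10.57. Such genes count among the MEF-high genes of the position scale, so part of each clone's distance from MEF may reflect them.

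Xist was near the mESC value in OKS clones 1 and 2, while Eif2s3y, a Y-linked gene, was 3.11 to 4.50 in all clones, 8.64 in mESC and 5.72 in MEF. Loss of X inactivation with 2 active X chromosomes would raise X-linked genes. The median of 329 X-linked genes in clones 1 and 2 over clone 3 was -0.0983 (log2, 95% bootstrap interval -0.181 to -0.0134) relative to 10808 autosomal genes, which argues against it. Loss of 1 X chromosome stays open, as a hypothesis not tested.

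Some clones had whole chromosomes shifted against the mean of the other clones, by a median of 0.35 and 0.34 (log2) for chromosome 19 in OKS 1 and OKS 2, 0.38 for chromosome 18 in OKSM 3 and 0.19 for chromosome 1 in OKS+F+G 6. A gained copy of the whole chromosome, as a hypothesis, should raise each of 4 equal parts of it above any block of as many neighbouring genes on other autosomes. This comparison replaced a fixed bound that had been set after the parts were seen. For chromosome 1 the lowest part had 69.2% of genes above the other clones against 52.6% in the highest of 56 blocks, a margin of 16.7 points, which met this criterion. Its blocks held 156 genes, against 95 for chromosome 19 and 70 for chromosome 18. Larger blocks vary less, so the margins cannot be compared between chromosomes. The median shift of chromosome 1 (0.19) was the smallest named here, so a gain is not shown by the margin alone. For chromosome 19 the margin was -1.05 points in OKS 2 (68.4% against 69.5%), though OKS 1 had 71.6% against 64.2%, and for chromosome 18 it was -13.7 points (59.2% against 72.9%), so a gain of the whole chromosome is neither shown nor excluded there. OKS clones 1 and 2 share the chromosome 19 shift, the low Xist and a correlation of 0.987, so a common founder may be asked about, and with both averaged 1 gene was called between OKS+F+G and OKS clones.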
